A study of Danio rerio with 16 samples.

How the data were processed

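The values used were the deposited counts, integers per gene in 1 table per library, with 31452 Ensembl genes in the same order in all 16 tables and a symbol for 31181 of them. Per the labels, the reads were processed on the Zv9 build of the zebrafish genome, total RNA was taken with TRIzol and DNase I, and libraries were made with standard Illumina protocols. The aligner, the counting tool, the annotation release and the strandedness are not given in the sources used here. The column headers mark each library as control or measured sample, and for 9 libraries the header also names a sequencing lane. A closing line of size factors in each table was dropped and not used. Gene symbols and chromosomes were those of the tables, completed with a table of 21028 gene IDs for matching older and newer symbols.

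Genes were kept with filterByExpr of edgeR over the 4 groups, which left 21650 genes. Counts were scaled with TMM factors, and 1 quasi-likelihood model (glmQLFit with the robust option, glmQLFTest) was fitted to all 16 libraries with the 4 groups as levels, which left 12 residual degrees of freedom. All tests were two-sided. The comparisons were insulin against PBS at 0.5 hours post injection (hpi), insulin against PBS at 4 hpi, the difference between these effects (an interaction contrast), and PBS at 4 hpi against PBS at 0.5 hpi. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and adjusted p values in the text are from edgeR unless another tool is named. Levels are CPM (edgeR's cpm over TMM-scaled library sizes), given as mean and SD over the 4 libraries of a group. Changes are log2 ratios with the standard error (SE) of the model, and a positive change means higher in insulin, or higher at 4 hpi for the comparison over time. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

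Before the data were examined, 33 lists of zebrafish genes were written for this tissue and treatment, covering insulin signalling and its inhibitors, metabolism, growth, the immediate-early, stress and clock responses, inflammation, and markers of blood cells, liver, intestine, pancreas, muscle, eye, neurons, skin and cartilage. Of the 1235 symbols written, 1134 (91.8%) matched a gene of the tables. Lists with at least 5 tested members were tested with limma's camera on voom values against all other genes, with a preset correlation between genes of 0.01, and adjusted over the lists. The same test with a correlation estimated for each list from these libraries, and fry, which asks whether the genes of a list moved on balance in 1 direction, were alternatives. For members of each list the count that passed is given over all genes tested and adjusted over the list alone. The comparisons, tests, lists and most alternatives were chosen at the same stage, with exceptions named below.

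Genes were named by a fixed rule, not claimed to predate the data. For each comparison of groups these were the 8 genes with the largest change in each direction among those that passed, had a symbol and averaged at least 1 log2 CPM (2 CPM). The gene of the series title, ptpn6, was always reported. From each list that passed its test the members with the smallest p were taken, 3 at 4 hpi and 2 elsewhere, and 1 member from each other list with 3 or more genes that passed. For the difference between times the 5 genes with the smallest p in each direction were taken. Other genes are said to have been chosen after their values were seen. A few genes that this rule or a small count would name are not reported here, and none took their place.

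The alternatives fixed in advance were DESeq2 size factors, library totals without TMM factors, the DESeq2 Wald test, limma voom, no filter on low counts, a filter of at least 10 CPM in 4 libraries, only the libraries of the groups compared, the replicate number of the titles as a block, and leaving out each library in turn. A further 7 alternatives were chosen after seeing the data, because 4 libraries stood apart from the rest, a pair of libraries was nearly identical, and the headers named lanes. These were a term for the library split, the 12 libraries without those 4, the near-identical pair summed as 1 library, the 12 libraries with that pair summed, the 12 libraries with the correlation of each list estimated, the lane 5 libraries alone, and the libraries with no lane in the header alone. The 4 libraries were defined by under 10 CPM of both wdr90 and si:dkey-15h8.1. Log2 CPM values for the principal components used a prior count of 2. ptpn6 was also compared with an exact two-sided permutation test on the 4 against 4 CPM values of each comparison.

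The model was tested on simulated data of 21456 genes with known changes. At 0.5 hpi it called 14.9% of genes changed by a log2 of 0.5, 62.1% of those changed by 1 and 92.1% of those changed by 2, with 6 false calls. At 4 hpi the shares were 17.9%, 64.2% and 98.4%, with 5 false calls, and in the simulated comparison over time, which held no change, 0 genes were called by edgeR. A list planted with a log2 change of 0.5 was recovered at both times, with 0 other lists called by camera. The simulated genes varied independently of each other, and no simulated library stood apart. The simulation thus does not measure false calls in the real libraries. There, other splits of the libraries at 0.5 hpi into groups of 4 called up to 18 lists and 294 genes. Isoforms, sequence variants and reads below the gene level were not analysed here.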

Results

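RNA was sequenced from whole zebrafish embryos of the ABTL background at 4 days post fertilization (dpf). Each embryo had received 1 nl of human recombinant insulin, or of PBS as the control, into the caudal aorta, and each library held a pool of 10 embryos. The 16 libraries formed 4 groups of 4, PBS and insulin at 0.5 hours post injection (hpi) and PBS and insulin at 4 hpi. Library totals were 7.58e+06 to 9.63e+06 reads for PBS and 7.93e+06 to 8.64e+06 for insulin at 0.5 hpi. They were 7.21e+06 to 9.60e+06 for PBS and 6.54e+06 to 9.18e+06 for insulin at 4 hpi. Mitochondrial genes took 3.55% to 4.21% of the reads, and the most abundant gene of a library took at most 1.87%. Of 31452 genes, 21650 were tested. The series title concerns hyperinsulinemia, insulin resistance and immune suppression, and names the phosphatase gene ptpn6.

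The first principal component held 31.2% of the variance and the second 16.0%. On the first, the PBS libraries at 4 hpi lay between 38.59 and 47.6 and the insulin libraries at 4 hpi between -52.8 and -11.4. A total of 4 libraries stood apart from the other 12: PBS replicate 1 and insulin replicates 1 and 2 at 0.5 hpi, and insulin replicate 1 at 4 hpi. They held 2.76 to 4.96 CPM of wdr90, against 32.1 to 94.9 CPM in the others, and 2.205 to 3.08 CPM of si:dkey-15h8.1, against 94.1 to 130 CPM. Against the other 12, these libraries had 15 of 24 erythroid markers higher and 0 lower (edgeR, adjusted p under 0.05, list median 0.72). Of the photoreceptor and lens markers 23 of 49 were lower and 1 higher (median -0.44). With an estimated correlation both lists had an adjusted p of 0.103. PBS replicates 2 and 3 at 0.5 hpi were nearly identical, with 89 of 20557 genes differing beyond counting error. Whether they are separate pools or 2 libraries of 1 sample was not settled. The means, SDs and tests for PBS at 0.5 hpi count them as 2 of 4. Summed as 1 library, they left 11 of the 84 genes called at 0.5 hpi and 1916 of the 2946 called over time in PBS.

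**Figure D1:**
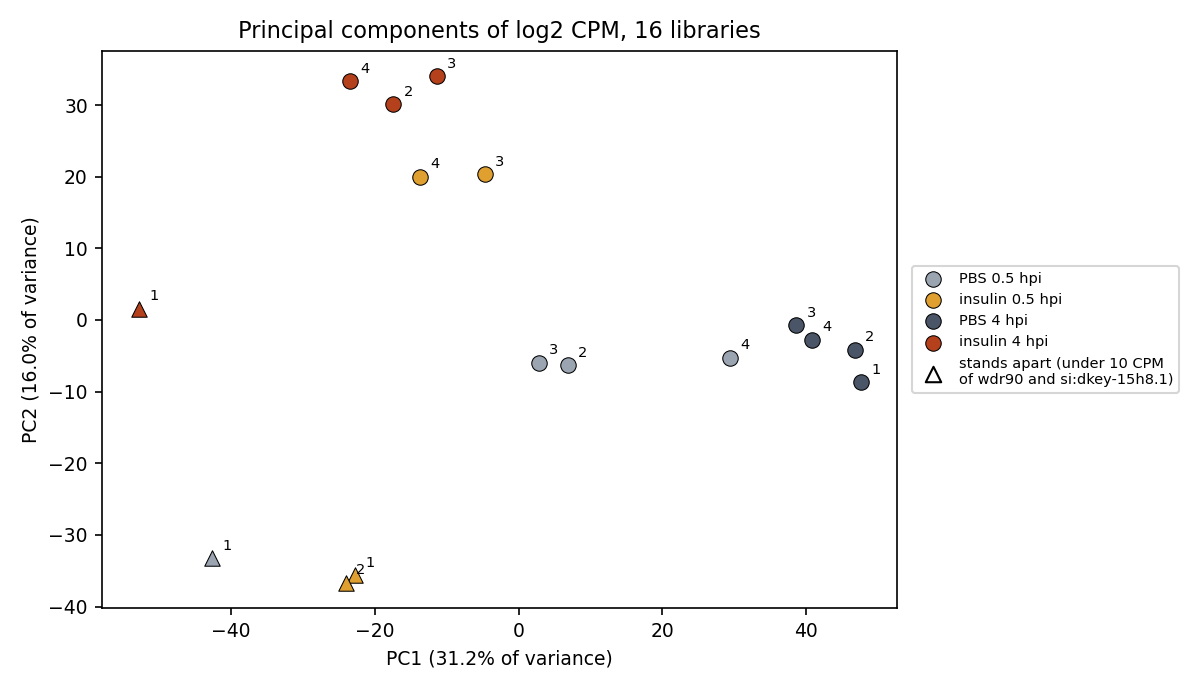
First and second principal component of log2 CPM (31.2% and 16.0% of the variance) for the 16 libraries, 1 point per library, with triangles for the 4 libraries that stand apart. The PBS libraries at 4 hpi lie together at the right, and 3 of the 4 triangles, all from 0.5 hpi, lie together at the lower left.

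The comparison at 0.5 hpi came first. pck1 (chromosome 6), which encodes the rate-limiting enzyme of gluconeogenesis, fell from 554 ± 111 CPM in PBS to 267 ± 24.8 CPM in insulin (SD, n = 4; log2 change -1.05, SE 0.14, adjusted p = 0.00626). All 4 insulin libraries (232 to 290 CPM) lay below all 4 PBS libraries (450 to 711 CPM). txnipa (chromosome 19) and txnipb (chromosome 16), whose products restrain glucose uptake, fell by 1.15 (SE 0.21) and 1.04 (SE 0.20), with an adjusted p of 0.0308 for each; without the 4 libraries that stand apart txnipb was at -1.72. igfbp1a (chromosome 20), which encodes a binding protein for insulin-like growth factors, fell from 81.1 ± 23.9 to 37.3 ± 8.95 CPM (log2 change -1.12, SE 0.23, adjusted p = 0.0412). The genes that rose included a pair of the photolyase and cryptochrome family, cry-dash (chromosome 24, log2 change 1.15, SE 0.21, adjusted p = 0.0308) and cry5 (chromosome 10, 1.62, SE 0.29, adjusted p = 0.0308; 2.25 without the 4 libraries). A pair of nucleotide excision repair genes, ercc6 (0.91, adjusted p = 0.00626) and ddb2 (1.096, adjusted p = 0.0394), also rose. cry-dash ranged from 22.2 to 26.3 CPM in PBS. It was 31.7 and 35.0 in insulin replicates 1 and 2, and 73.0 and 70.8 in replicates 3 and 4. Different light exposure was not excluded. The other large increases were those of wdr76 (1.57, adjusted p = 0.00626), dhrs12 (0.93, adjusted p = 0.00626), zufsp (0.94, adjusted p = 0.0294) and glcea (0.85, adjusted p = 0.0308). The other large decreases were those of the sarcomere gene tcap (-1.63, adjusted p = 0.0425), ZMAT1 (-1.44, adjusted p = 0.0308), arrdc2 (-1.23, adjusted p = 0.0308) and the angiopoietin receptor gene tek (-1.16, adjusted p = 0.0390).

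In all, 84 genes passed at 0.5 hpi, 36 higher and 48 lower, 22 of them by over 2-fold, and 2809 genes had an unadjusted p under 0.05. DESeq2 called 483 genes, 79 of them shared. With library totals in place of TMM factors 71.6% of the called genes were higher, against 42.9% with TMM, and tcap, igfbp1a, trib3, tek and pim1 did not pass (adjusted p from 0.0604 to 0.0769). Of the 21 named genes that passed, pck1, dhrs12 and wdr76 passed without any single library. ercc6 did not pass without insulin replicate 4 (adjusted p = 0.0528), and the other 17 did not pass without PBS replicate 2, 3 or 4 or insulin replicate 3 or 4 (adjusted p from 0.0533 to 0.180), klf2a excepted for insulin replicate 4. In the same range igfbp1a, pim1, tek, trib3 and tcap did not pass without insulin replicate 2, or tcap without insulin replicate 1. Without PBS replicates 2, 3 and 4 and insulin replicates 3 and 4 in turn the count was 10, 11, 13, 12 and 12, and without PBS replicate 1, which stands apart, it was 987. Among the 12 libraries that do not stand apart, 3 PBS and 2 insulin at 0.5 hpi, 2844 genes passed, with all 84 among them. Of 2834 genes scaled on these libraries, 1211 ran as labelled in the 3 at 0.5 hpi that stand apart and 1623 the other way. A fit with the library split as a term gave 493, and with PBS replicates 2 and 3 summed 11 passed. By edgeR 0 genes passed among the libraries with no lane in the header (654 at an unadjusted p under 0.05) and 0 in a fit of the groups compared alone (2115 at an unadjusted p under 0.05).

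Among the lists fixed in advance, 19 of 33 passed at 0.5 hpi, 3 higher and 16 lower, and 11 of these held no gene that passed by itself. With an estimated correlation 0 lists passed by camera (5 at an unadjusted p under 0.05), and fry called 3. Of 46 immediate-early genes, which respond to growth factors and stress within minutes, 4 fell and 0 rose over all genes tested, and 29 fell adjusted over the list alone (median -0.47, adjusted p = 1.68e-25; adjusted p = 0.0759 with an estimated correlation). The 4 were jun (-0.80, SE 0.14, adjusted p = 0.0247), klf2a (-0.57, SE 0.11, adjusted p = 0.0294) and, chosen after their values were seen, egr3 (-0.84) and spry4 (-0.47). Of 37 FoxO and fasting targets 4 fell, and 14 adjusted over the list alone (median -0.29, adjusted p = 8.51e-12; adjusted p = 0.0759 with an estimated correlation); they were pck1, txnipa, igfbp1a and, chosen after its value was seen, klf11b (-0.67). Of 22 glucocorticoid and stress genes pck1 fell, and 8 adjusted over the list alone, and cebpb did not pass (-1.12, adjusted p = 0.0523; list median -0.23, adjusted p = 3.68e-07; adjusted p = 0.254 with an estimated correlation). In the gluconeogenesis list pck1 was the only 1 of 18 genes that fell, 2 adjusted over the list alone, and g6pca.1, for glucose-6-phosphatase, did not pass (-0.66, adjusted p = 0.0622; list median -0.20, adjusted p = 0.00129; adjusted p = 0.230 with an estimated correlation). In the hypoxia list igfbp1a was the only 1 of 29 that fell, 4 adjusted over the list alone, and igfbp1b was at -1.05 without passing (median -0.13, adjusted p = 0.00129; adjusted p = 0.269 with an estimated correlation). Of 32 JAK-STAT genes the kinase genes pim2 (-0.85, adjusted p = 0.0308) and pim1 (-0.52, adjusted p = 0.0412) fell, and 1 rose and 2 fell adjusted over the list alone (median -0.15, adjusted p = 0.00286; adjusted p = 0.269 with an estimated correlation). Of 43 genes of glycolysis and glucose uptake 3 fell, among them txnipa and txnipb, with the same count adjusted over the list alone (median -0.05, adjusted p = 0.0222; adjusted p = 0.398 with an estimated correlation). Of 41 heat-shock and unfolded-protein genes trib3 fell (-0.84, adjusted p = 0.0488), with 1 up and 3 down adjusted over the list alone, and hsf2 was at 0.47 without passing (median -0.06, adjusted p = 0.0191; adjusted p = 0.571 with an estimated correlation).

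A further 11 lists passed at 0.5 hpi with 0 members called by edgeR over all genes tested. For these lists the adjusted p with an estimated correlation ran from 0.194 to 0.696. Of 44 proinflammatory genes 2 fell adjusted over the list alone (median -0.15, adjusted p = 0.000482), and cebpd was at -0.90 without passing (adjusted p = 0.0628). Of 45 acute-phase and complement genes 4 fell adjusted over the list alone (median -0.10, adjusted p = 0.000482), with C7 (2 of 2) at -1.48 and cp at -0.58, neither passing. The 25 macrophage markers had a median of -0.15 (adjusted p = 0.0445; ctssb.1 -0.65 and lgals9l1 -0.54) and the 19 neutrophil markers a median of -0.17 (adjusted p = 0.0165; mmp13a -0.60 and cebpa -0.29), with 0 members called by edgeR adjusted over the list alone. Of 26 skin markers 1 fell adjusted over the list alone (median -0.21, adjusted p = 1.35e-05; col17a1b -0.48, epcam -0.43), as did 7 of 45 muscle markers (median -0.09, adjusted p = 7.79e-05; casq1a -0.43, myha -0.44) and 2 of 37 liver markers (median -0.09, adjusted p = 0.0445; gc -0.69). The 33 cartilage, bone and matrix genes had a median of -0.06 (adjusted p = 0.0466; fn1b -0.37, sox9b -0.30). The 3 lists that moved up were 40 genes of growth and ribosome biogenesis (median 0.25, adjusted p = 3.02e-08; nip7 0.60, gnl3 0.49), 55 cell cycle genes (median 0.12, adjusted p = 0.0147; cenpf 0.51, mcm5 -1.25) and 28 cholesterol synthesis genes (median 0.21, adjusted p = 0.0165; hmgcra 0.71, insig1 -0.45). These held 0 members called by edgeR adjusted over the list alone. Within their groups the 4 libraries that stand apart, 1 PBS and 2 insulin here, had higher medians than the others for some lists. These were liver (0.34), muscle (0.25), skin (0.26), neutrophil (0.33), macrophage (0.26), cholesterol (0.35), growth (0.24), cell cycle (0.24) and heat-shock (0.18). In the 12 libraries that do not stand apart the liver list had a median of 0.01 (adjusted p = 0.606), the cartilage list 0.07 (adjusted p = 0.261) and the neutrophil list -0.20 (adjusted p = 0.0568), and none of these passed. The other 8 of these lists passed there. In the growth list 26 of 40 genes rose and 0 fell (median 0.51, adjusted p = 9.44e-20), in the cholesterol list 12 rose and 1 fell (median 0.47, adjusted p = 9.20e-09) and in the cell cycle list 7 rose and 2 fell (median 0.23, adjusted p = 0.000263). These 3 did not pass in the 12 libraries with an estimated correlation (adjusted p = 0.0891, 0.0634 and 0.444).

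Some of these calls rested on single libraries at 0.5 hpi. Without PBS replicate 1 the heat-shock (adjusted p = 0.0526), neutrophil (0.276), macrophage (0.666), muscle (0.151) and cartilage (0.638) lists did not pass, and the liver list had a median of 0.00 (adjusted p = 0.870). The heat-shock and cartilage lists were also lost without PBS replicate 2 (0.0540 and 0.0808) or replicate 3 (0.0563 for each), and the cholesterol list without PBS replicate 2 (0.0540). Without PBS replicate 4 the glycolysis, JAK-STAT and macrophage lists (0.0549 each), the cholesterol list (0.0615) and the cell cycle list (0.937) did not pass. Without insulin replicate 1 the liver (0.313) and cartilage (0.104) lists did not pass, and without insulin replicate 2 the cartilage list (0.541, with its median at 0.0179). Without insulin replicate 3 the cholesterol (0.0896), neutrophil (0.0558), macrophage (0.423) and liver (0.0547) lists did not pass, and without insulin replicate 4 the cholesterol (0.105), cell cycle (0.0511) and macrophage (0.164) lists.

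The 14 other lists did not pass at 0.5 hpi (adjusted p from 0.0622 to 0.968). In the clock list, of 47 genes, cry5 and, chosen after its value was seen, tefa (0.77) rose, and 4 rose and 9 fell adjusted over the list alone (median 0.06, mean -0.01). Of 49 photoreceptor and lens markers arr3a rose, chosen after its value was seen (0.80), and 2 rose adjusted over the list alone (median 0.11, mean -0.09, test direction down). In the 36 inhibitors of insulin signalling trib3 fell, also adjusted over the list alone (median -0.03). Adjusted over the list alone 2 of 28 fatty acid oxidation genes (median -0.02) and 1 of 23 islet markers (median -0.03) fell. The medians were -0.01 for 40 insulin signalling genes, 0.00 for 27 lipogenesis genes, 0.00 for 20 intestine markers (mean -0.05) and -0.02 for 15 interferon genes (mean 0.03, test direction down). With library totals these 4 medians and those of the inhibitor, fatty acid and islet lists lay above 0. The medians of the remaining lists were -0.22 for 15 lymphoid markers, -0.09 for 27 pattern recognition genes, 0.08 for 35 neuron markers, 0.07 for 24 erythroid markers (mean 0.08, test direction down) and 0.23 for 30 exocrine pancreas markers. In the 12 libraries that do not stand apart 3 of these 14 lists passed, the exocrine list up (median 0.71, adjusted p = 1.49e-09), the intestine list up (0.13, adjusted p = 0.0270) and the clock list down (-0.04, adjusted p = 0.0226), with 5 clock genes up and 13 down. None of the 3 passed there with an estimated correlation (adjusted p = 0.357, 0.444 and 0.444).

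The comparison at 4 hpi began with clock genes. cry3 (chromosome 25) fell from 140 ± 7.998 CPM in PBS to 21.1 ± 1.61 CPM in insulin (SD, n = 4; log2 change -2.73, SE 0.12, adjusted p = 2.22e-11). per1b (chromosome 7) fell from 225 ± 8.67 to 56.3 ± 3.88 CPM (-1.999, SE 0.10, adjusted p = 3.76e-11) and cry1b (chromosome 18) from 70.5 ± 5.12 to 15.01 ± 1.0099 CPM (-2.23, SE 0.12, adjusted p = 1.53e-10). per1b and cry1b encode repressors of the circadian clock. In each of the 3 genes the 4 insulin libraries lay below the 4 PBS libraries, as for per1b at 52.4 to 60.4 against 217 to 236 CPM. nr1d4b, of the nuclear receptor family that represses the clock activator arntl, fell by 3.37 (SE 0.37, adjusted p = 2.07e-05). Of the 47 clock genes tested 36 fell and 1 rose over all genes tested, and 38 fell and 1 rose adjusted over the list alone (median -0.93, adjusted p = 1.04e-23; adjusted p = 0.0726 with an estimated correlation). The gene that rose was cry2a (1.22, SE 0.12, adjusted p = 5.84e-07), chosen after its value was seen. In the 12 libraries that do not stand apart the median was -0.98. Between the 4 libraries that do and the others the list median was -0.16.

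Genes of the immediate-early and inflammatory responses were lower in insulin at 4 hpi. The AP-1 genes fos, fosb, fosl1a and junbb fell by 3.63, 3.33, 4.02 and 1.96, with adjusted p from 3.00e-06 to 6.98e-05, and fos went from 94.3 ± 13.1 to 7.50 ± 2.86 CPM (SD, n = 4). Of 46 immediate-early genes 31 fell and 4 rose, and 32 fell and 5 rose adjusted over the list alone (median -0.83, adjusted p = 4.18e-11; adjusted p = 0.338 with an estimated correlation). The phosphatase gene dusp5 was among those that fell (-2.24, adjusted p = 2.23e-07), and the 4 that rose, chosen after their values were seen, were klf2a (0.57), zfp36l2 (0.48), spry2 (0.45) and nr4a2a (0.36). The cytokine gene il1b (chromosome 10) fell from 23.9 ± 10.9 to 2.03 ± 0.284 CPM (log2 change -3.53, SE 0.33, adjusted p = 9.58e-07), with 12.4 to 33.3 CPM in the PBS libraries and 1.73 to 2.28 CPM in the insulin libraries. The collagenase gene mmp13a fell by 3.01 (SE 0.23, adjusted p = 2.23e-07), the cyclooxygenase gene ptgs2b by 3.36 (adjusted p = 4.65e-05) and the TNF receptor gene tnfrsf9a by 1.58 (adjusted p = 6.08e-06). irg1l also fell (log2 change -3.87, adjusted p = 0.00409). Of 44 proinflammatory genes 29 fell and 1, nos2b (0.65, chosen after its value was seen), rose, with the same counts adjusted over the list alone (median -1.30, adjusted p = 6.16e-12; adjusted p = 0.241 with an estimated correlation). The median was -1.38 in the 12 libraries that do not stand apart. plek2, outside the lists, showed the largest decrease among the named genes, from 67.0 ± 25.1 to 3.62 ± 1.19 CPM (log2 change -4.19, SE 0.39, adjusted p = 6.37e-06).

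Of 22 glucocorticoid and stress genes 12 fell, among them per1a (-2.64, adjusted p = 2.23e-07) and the kinase gene sgk1 (-1.64, adjusted p = 5.27e-06), and crhb rose (1.04, chosen after its value was seen), with the same counts adjusted over the list alone (median -0.58, adjusted p = 1.80e-05; adjusted p = 0.338 with an estimated correlation). Of 32 JAK-STAT genes 12 fell and 0 rose, with the same counts adjusted over the list alone, among them the feedback inhibitor socs3b (-1.17, adjusted p = 5.55e-05), the prolactin receptor gene prlrb (-1.47, adjusted p = 0.000134) and pim1 (-0.67, adjusted p = 0.000196; list median -0.33, adjusted p = 0.000576; adjusted p = 0.338 with an estimated correlation). Of 37 FoxO and fasting targets 13 fell and 2 rose, and 13 fell and 3 rose adjusted over the list alone (median -0.30, adjusted p = 0.000978; adjusted p = 0.338 with an estimated correlation). The ubiquitin ligase gene fbxo32, which acts in muscle protein breakdown, fell from 12.4 ± 1.58 to 3.36 ± 0.529 CPM (log2 change -1.87, SE 0.23, adjusted p = 1.54e-05), pik3ip1, for an inhibitor of PI3 kinase, by 1.11 (adjusted p = 2.85e-05) and the autophagy receptor gene sqstm1 by 0.98 (adjusted p = 0.000158). The 2 that rose were cdkn1ba (0.40) and cited2 (0.28), chosen after their values were seen.

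Several groups moved up at 4 hpi. serpinh1b (chromosome 15), which encodes a chaperone of collagen, rose from 12.8 ± 1.49 to 123 ± 50.5 CPM (log2 change 3.27, SE 0.24, adjusted p = 1.80e-07). It lay at 11.3 to 14.4 CPM in the PBS libraries and 91.4 to 199 CPM in the insulin libraries, the highest in replicate 1, which stands apart. Of 41 heat-shock and unfolded-protein genes 19 rose and 5 fell, and 20 rose and 5 fell adjusted over the list alone (median 0.53, adjusted p = 0.00783; adjusted p = 0.619 with an estimated correlation). Those that fell were hsf2 (-1.05, adjusted p = 4.77e-06), bag3 (-0.73, adjusted p = 5.55e-05) and, chosen after their values were seen, trib3 (-1.18), hsf1 (-0.73) and hspb8 (-0.49). Of 30 exocrine pancreas markers, mostly digestive enzymes, 14 rose and 0 fell, and 21 rose adjusted over the list alone (median 0.96, adjusted p = 6.45e-06; adjusted p = 0.619 with an estimated correlation). cpa1, for carboxypeptidase A1, went from 14.8 ± 2.23 to 32.3 ± 4.84 CPM (log2 change 1.12, SE 0.32, adjusted p = 0.0169), ctrl was higher by 1.09 (adjusted p = 0.0234) and ERP27 by 0.79 (adjusted p = 0.0176). cpa1 did not pass without PBS replicate 1 or 2 (adjusted p = 0.05004 and 0.0521), ctrl without PBS replicate 1 or 2 or insulin replicate 3 (0.0682, 0.0660 and 0.0665), and ERP27 without PBS replicate 1 or insulin replicate 4 (0.0701 and 0.0534). Of 55 cell cycle genes 24 rose and 5 fell, and 29 rose and 6 fell adjusted over the list alone, and the list median was 0.39 (adjusted p = 8.46e-06; adjusted p = 0.619 with an estimated correlation). The mitotic genes cdc20 (1.31, adjusted p = 5.02e-05), tpx2 (0.97, adjusted p = 1.04e-05) and plk1 (0.93, adjusted p = 3.62e-05) rose. Between the 4 libraries that stand apart, of which insulin replicate 1 is at this time, and the other 12, the median was 0.18 for the heat-shock list, -0.53 for the exocrine list and 0.24 for the cell cycle list. The insulin medians in the 12 libraries were 0.33, 1.11 and 0.30.

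Of 20 intestine markers 8 rose and 0 fell, with the same counts adjusted over the list alone, among them the aminopeptidase gene anpepb (1.02, SE 0.12, adjusted p = 4.99e-06), tm4sf5 (0.93, adjusted p = 0.00281) and agr2 (0.66, adjusted p = 0.00275; list median 0.59, adjusted p = 0.00349; adjusted p = 0.619 with an estimated correlation). Of 37 liver markers 9 rose and 2 fell, with the same counts adjusted over the list alone (median 0.36, adjusted p = 0.00377; adjusted p = 0.663 with an estimated correlation). cyp8b1, of bile acid synthesis, rose by 1.42 (adjusted p = 0.000507) and the hepatic transcription factor gene hnf4a by 0.90 (adjusted p = 0.00110), and cp, for ceruloplasmin, fell by 0.76 (adjusted p = 0.00120), as did apobb (-0.37, chosen after its value was seen). Of 40 genes of growth and ribosome biogenesis nat10 (0.65), ddx10 (0.65), bop1 (0.54) and, chosen after their values were seen, rrp9 rose and nop2 fell (-0.44), and 3 rose and 0 fell adjusted over the list alone (median 0.20, adjusted p = 0.0206; adjusted p = 0.823 with an estimated correlation). Without insulin replicate 1, which stands apart, the growth list (median 0.10, adjusted p = 0.327) and the liver list (0.16, adjusted p = 0.0875) did not pass, and the liver and growth medians were 0.34 and 0.24 higher in the 4 libraries that stand apart. Outside the lists the largest increases were those of lrata (3.06, SE 0.47, adjusted p = 0.000135), which makes retinyl esters, ponzr4 (2.82, adjusted p = 0.000147), ugt5d1 (2.18, adjusted p = 0.000103), SNORD47 (1.92, adjusted p = 0.00180) and the splicing kinase gene clk4a (1.87, SE 0.11, adjusted p = 6.39e-10). clk4a went from 61.7 ± 5.59 to 225 ± 16.2 CPM.

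Metabolic genes moved in different directions at 4 hpi, and none of their lists passed camera. gck, for glucokinase, rose from 5.82 ± 2.82 to 22.5 ± 5.21 CPM (log2 change 1.96, SE 0.33, adjusted p = 0.000411), and pfkfb3, for an activator of glycolysis, fell from 101 ± 14.7 to 24.5 ± 7.59 CPM (-2.03, SE 0.26, adjusted p = 5.46e-05). lpin1, for a phosphatidate phosphatase, fell by 2.15 (adjusted p = 7.13e-07), ppargc1b by 0.98 (adjusted p = 3.89e-06) and pparda by 0.68 (adjusted p = 0.000447). The transcription factor gene foxo1a, which insulin signalling restrains, fell by 1.31 (SE 0.17, adjusted p = 1.81e-05), and egln3, of oxygen sensing, rose by 1.90 (adjusted p = 0.00132). By list, 9 genes rose and 6 fell of 43 in glycolysis (11 and 6 adjusted over the list alone; median 0.11), 8 and 9 of 27 in lipogenesis (the same over the list alone; median -0.07). They were 5 and 3 of 28 in cholesterol synthesis (the same; median 0.18), 11 and 6 of 28 in fatty acid oxidation (12 and 6; median 0.27) and 4 and 3 of 18 in gluconeogenesis (the same; median 0.15). Of 40 insulin signalling genes 4 rose and 14 fell, and 5 and 15 adjusted over the list alone (median -0.19, adjusted p = 0.0560). Of 29 hypoxia genes 2 rose and 9 fell, with the same counts adjusted over the list alone (median -0.21). The adjusted p of the list tests of this paragraph ran from 0.0560 to 0.711.

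The immune, blood and tissue lists in this paragraph and the inhibitors of insulin signalling did not pass camera at 4 hpi in all 16 libraries. Of the 36 inhibitors of insulin signalling 4 rose and 6 fell, and 5 and 6 adjusted over the list alone (median -0.06). Both ptpn6 identifiers, which are not known to be separate genes, were among the 4 that rose, and trib1 fell (-1.76, adjusted p = 2.83e-05). Of 25 macrophage markers 6 rose and 1 fell (median 0.20), of 19 neutrophil markers 0 rose and 4 fell (median -0.09), each with the same counts adjusted over the list alone. The macrophage list also holds ptpn6, so both identifiers are among its 6 genes that rose. Others, chosen after their values were seen, were mfap4 (1.17), coro1a (0.78) and CD68 (0.53), while mpeg1 did not pass (0.17). Of 27 pattern recognition genes 0 rose and 8 fell (median -0.05), among them ripk2 (-1.67, adjusted p = 9.58e-07), and of 15 interferon genes 0 rose and 3 fell (median -0.48), among them irf7 (-1.33, adjusted p = 0.000366). Of 45 acute-phase and complement genes 3 rose and 6 fell (median -0.01), among them C7 (2 of 2) (-2.01, adjusted p = 0.000205), and the counts of these 3 lists were the same adjusted over the list alone. For the lists of this paragraph the adjusted p of the list test lay between 0.127 and 0.953, apart from 0.0788 for the interferon list. The macrophage median was 0.26 and the neutrophil median 0.33 higher in the 4 libraries that stand apart. Of 15 lymphoid markers 0 rose and 3 fell, 2 adjusted over the list alone, among them tagapa (-1.51; list median 0.11, mean -0.05, test direction down). The counts of genes that rose and fell were 5 and 3 of 49 photoreceptor and lens markers (guca1a -1.89; median 0.11), 4 and 1 of 23 islet markers (median 0.10) and 4 and 2 of 33 cartilage genes (sox9b 0.76; median 0.09), each the same adjusted over the list alone. They were 7 and 8 of 45 muscle markers (9 and 8 adjusted over the list alone; ryr1b -0.76; median 0.16), 2 and 2 of 24 erythroid markers (2 and 1; sptb -0.58; median 0.13). For the last lists they were 4 and 6 of 26 skin markers (5 and 6; epcam -0.95; median 0.14) and 3 and 2 of 35 neuron markers (3 and 1; stmn2b 0.82; median 0.05, below 0 with library totals). In the 12 libraries that do not stand apart the lens list passed (median 0.26, adjusted p = 0.000143), as did the hypoxia list (-0.32, adjusted p = 0.0479), and the liver (0.15, adjusted p = 0.0516) and growth (0.10, adjusted p = 0.225) lists, which passed in all 16, did not. With an estimated correlation the lens (adjusted p = 0.396) and hypoxia (0.498) lists did not pass there.

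The genes behind counts of 5 or fewer at 4 hpi, where not named by the fixed rule, were chosen after their values were seen. In metabolism got1, GPT (3 of 5), fbp2 and fbp1a rose and pck1 fell in gluconeogenesis. MVD, dhcr7, nsdhl, cyp51 and lss rose and insig1 was among those that fell in cholesterol synthesis, and p4ha1b rose in the hypoxia list. In insulin signalling eif4ebp1, akt2l, tsc1a and tsc2 rose, and among its inhibitors ptpn2b and inpp5d. Of the cell cycle genes e2f7, e2f8, cdt1 and 2 genes with the symbol rrm2 fell. Of the immune and blood lists, rbp4, cfd, c8b, creg1 and aqp1a.1 rose, and stat2, irf3, mmp9, ncf1, cebpa, ctssb.1, sla2, pax5 and fech fell, as did mmp13a in the neutrophil list. Of the tissue markers, nkx2.2a, slc30a8 and sst1.1 in islets, the cone opsin genes opn1sw2, opn1mw1, opn1lw1, opn1mw2 and opn1lw2, and inaa and tph2 in neurons rose. So did krt1-19d, cldn1, pycard and zgc:109868 in skin and sox9a, col1a1a and col1a1b in cartilage. Those that fell were pcsk1 in islets, nr2e3 and guca1c in photoreceptors, map1aa and nefma in neurons and timp2a and timp2b in cartilage.

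ptpn6 encodes a tyrosine phosphatase and was also on the list of macrophage markers. There are 2 gene identifiers with this symbol on chromosome 16. Whether they are 2 genes or parts of 1 gene model was not settled, so the 2 results are not counted as independent. The first (ENSDARG00000013916) rose at 4 hpi from 1.67 ± 0.289 to 4.93 ± 0.719 CPM (SD, n = 4; log2 change 1.56, SE 0.31, adjusted p = 0.00101), with 1.43 to 1.98 CPM in the PBS libraries and 4.29 to 5.63 CPM in the insulin libraries. The second (ENSDARG00000089043) rose from 1.23 ± 0.427 to 2.68 ± 0.598 CPM (log2 change 1.12, SE 0.30, adjusted p = 0.00975), with 0.815 to 1.78 against 1.95 to 3.33 CPM. The exact two-sided permutation test gave p = 0.0286 for each, the smallest that 4 against 4 libraries allow. At 0.5 hpi the first was at -0.17 (SE 0.30, adjusted p = 0.877) and the second at -0.00 (SE 0.26, adjusted p = 1.00). The insulin effect of the first differed between the times (1.73, adjusted p = 0.0155), and that of the second was not shown to differ (1.12, adjusted p = 0.0887). Over time in PBS the second fell by 1.03 (adjusted p = 0.0284) and the first was at -0.86 (adjusted p = 0.0802). The second lost this call without PBS replicate 1, 2 or 4 at 0.5 hpi or PBS replicate 1, 2 or 3 at 4 hpi (adjusted p from 0.0538 to 0.104). Counts behind these values were 8 to 52 reads per library. In the lane 5 libraries alone the changes at 4 hpi were 1.58 (adjusted p = 0.0127) and 1.39 (adjusted p = 0.0429).

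**Figure D2:**
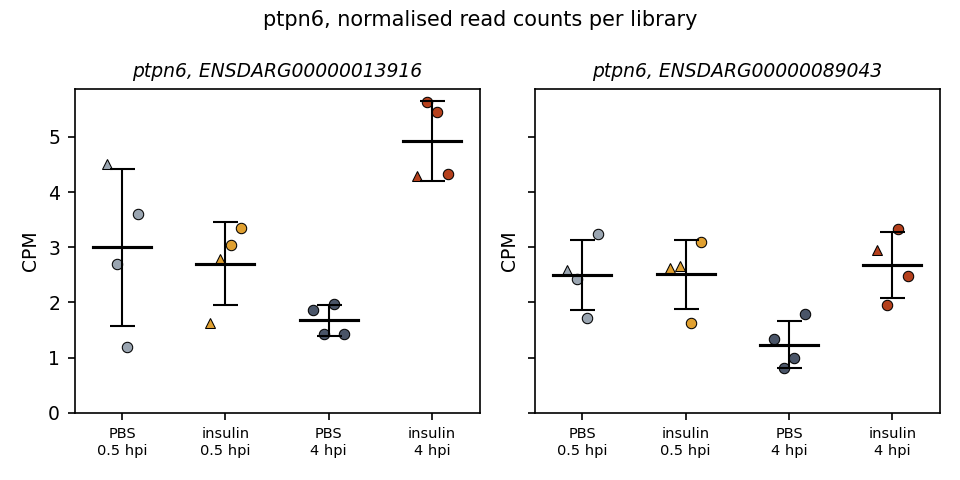
CPM of the 2 gene identifiers with the symbol ptpn6 in the 16 libraries by group, 1 point per library, triangles for the 4 libraries that stand apart, bars for mean and SD of 4 libraries. For both identifiers the insulin libraries at 4 hpi lie above the PBS libraries at 4 hpi, and the groups overlap at 0.5 hpi.

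At 4 hpi 6193 genes passed, 28.6% of those tested, 3035 higher and 3158 lower, 1207 of them by over 2-fold. DESeq2 called 6247, 5991 of them shared. With library totals 38.8% of the called genes were higher, against 49.0% with TMM. There were 7746 genes that passed in the 12 libraries that do not stand apart (5802 shared), 6840 with the library split as a term (5958 shared) and 2952 in the lane 5 libraries alone, 3 PBS and 2 insulin (2752 shared). Of 33 lists 12 passed, 6 up and 6 down, and with an estimated correlation 0 did by camera (4 at an unadjusted p under 0.05; fry called 15).

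The difference between the effects at 4 and 0.5 hpi was tested in itself. The clock genes cry3 (-2.80, SE 0.16, adjusted p = 1.89e-09), cry1b (-2.53, SE 0.16, adjusted p = 6.95e-09) and per1b (-1.76, SE 0.13, adjusted p = 1.02e-07) had a lower effect at 4 hpi. So did lonrf1l (-2.98, adjusted p = 1.26e-09) and the lysosomal channel gene mcoln1a (-1.80, adjusted p = 2.56e-07). The genes with a higher effect at 4 hpi included clk4a (1.78, SE 0.15, adjusted p = 4.76e-07) and a pair of genes for RNA-binding proteins, rbm4.2 (1.83, adjusted p = 1.35e-06) and safb (1.33, adjusted p = 2.13e-06). The stress gene nupr1 (1.93, adjusted p = 1.01e-06) and eif2ak3, for the kinase PERK of the unfolded protein response (1.39, adjusted p = 2.13e-06), were also among them. nupr1 went from 56.6 ± 9.90 in PBS to 44.5 ± 2.24 CPM in insulin at 0.5 hpi and from 37.0 ± 5.51 to 111 ± 5.60 CPM at 4 hpi (SD, n = 4). In all 2076 genes differed, 830 with a higher and 1246 with a lower effect at 4 hpi, and DESeq2 called 2404 (2018 shared). With library totals the median over all genes shifted to -0.10, from 0.01 with TMM, and the share of called genes with a higher effect was 22.8%, against 39.98%. Among the 12 libraries that do not stand apart 2880 genes passed (1571 shared), and with the library split as a term 3448 (2075 shared).

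Genes called at both times were compared next. Of 48 genes lower in insulin at 0.5 hpi 29 were also lower at 4 hpi, against 7.002 with independent calls (odds ratio 9.01, Fisher's exact test, two-sided p = 3.37e-13), and they included pck1, txnipa, igfbp1a, trib3, arrdc2, pim1 and pim2. pck1 was at 692 ± 86.5 CPM in PBS and 397 ± 62.9 CPM in insulin at 4 hpi (SD, n = 4). Of 36 genes higher at 0.5 hpi 4 were also higher at 4 hpi, against 5.05 with independent calls (Fisher's exact test, p = 0.811). They were C2H6orf52, cd99l2, adnpb and dcun1d4, chosen after their values were seen. A further 19 genes passed in opposite directions, among them cry-dash, dhrs12, ercc6, wdr76 and zufsp, higher at 0.5 and lower at 4 hpi, and klf2a, txnipb and ZMAT1, lower at 0.5 and higher at 4 hpi. dhrs12 went from 15.8 ± 2.72 to 30.2 ± 4.52 CPM at 0.5 hpi and from 38.7 ± 3.17 to 26.7 ± 2.66 CPM at 4 hpi. The times shared the dispersion estimate but no library. Fisher's test takes genes, not pools, as independent units. Genes able to pass at 1 time may pass more readily at the other, so 7.002 may be too low. With each time fitted alone the overlap of 33 was 0 by edgeR, since 0 genes passed at 0.5 hpi (2115 at an unadjusted p under 0.05). The 5 other alternatives, DESeq2 among them, gave more shared genes.

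The PBS groups gave the background of time after injection, handling and hour of collection. The insulin comparison at 4 hpi uses the same PBS libraries at 4 hpi with the opposite sign. Opposite changes in these comparisons are thus not independent. Inflammatory genes rose: mmp13a from 16.6 ± 1.39 CPM at 0.5 hpi to 144 ± 45.7 CPM at 4 hpi (SD, n = 4; log2 change 3.12, SE 0.23, adjusted p = 9.85e-07). The gelatinase gene mmp9 rose by 2.42 (adjusted p = 0.000158), the chemokine gene cxcl-c1c by 2.91 (adjusted p = 0.00350) and irg1 by 2.32 (adjusted p = 1.96e-05). The leptin gene lepb rose from 0.295 ± 0.295 to 6.56 ± 4.02 CPM (log2 change 4.47, SE 0.75, adjusted p = 0.00129). Other large increases were those of acsl4l (2.74, adjusted p = 1.89e-08), bcl3 (2.62, adjusted p = 4.81e-06) and irak3 (2.36, adjusted p = 0.000276), and bcl3 and irak3 both encode regulators of NF-kB signalling. The immediate-early gene egr1 fell from 311 ± 42.6 to 76.5 ± 11.8 CPM (-2.02, SE 0.16, adjusted p = 3.47e-07). The genes olfm2b (-2.24), foxq1a (-2.004), jdp2 (-1.92), txnipb (-1.69), the ammonium transporter gene rhcga (-2.04), ponzr4 (-2.53) and ponzr3 (-2.26) fell with adjusted p from 3.18e-06 to 0.00783.

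By list, 12 of 33 passed over time in PBS, 7 up and 5 down, and 0 did by camera with an estimated correlation (1 at an unadjusted p under 0.05; fry called 12). The adjusted p with an estimated correlation was 0.474 for these lists, apart from 0.497 for the skin and 0.811 for the muscle list. Of 44 proinflammatory genes 22 rose and 0 fell, and 25 rose adjusted over the list alone (median 0.76, adjusted p = 1.24e-08). Of 55 cell cycle genes 0 rose and 19 fell, and 23 fell adjusted over the list alone (tpx2 -0.74, plk1 -0.69; median -0.38, adjusted p = 4.40e-08). Of 46 immediate-early genes 3 rose and 18 fell, and 4 and 21 adjusted over the list alone (btg2 -1.54; median -0.26, adjusted p = 7.21e-05). Of 47 clock genes 16 rose and 2 fell, and 19 and 4 adjusted over the list alone (tefa 1.13, cry1b 0.99; median 0.19, adjusted p = 0.000204). Of 33 cartilage genes 2 rose and 7 fell, and 2 and 13 adjusted over the list alone (timp2b 1.81, sox9b -0.51; median -0.29, adjusted p = 0.000251). Of 32 JAK-STAT genes 9 rose and 0 fell, with the same counts adjusted over the list alone (il6st 1.34, socs3b 1.11; median 0.17, adjusted p = 0.00752). Of 26 skin markers 4 rose and 7 fell, and 4 and 11 adjusted over the list alone (epcam 0.65, col17a1b -0.67; median -0.30, adjusted p = 0.0101). Of 45 muscle markers 0 were called by edgeR over all genes tested or adjusted over the list alone (acta1a -0.40, actc1b -0.38, neither passing; median -0.21, adjusted p = 0.00658). Of 19 neutrophil markers 4 rose and 2 fell, with the same counts adjusted over the list alone (median 0.30, adjusted p = 0.0143). Of 27 lipogenesis genes 8 rose and 1 fell, with the same counts adjusted over the list alone (median 0.17, adjusted p = 0.0282), with increases of 0.93 and 1.09 for 2 genes with the symbol fasn, for fatty acid synthase. Of 15 interferon genes irf3 rose (0.85), 0 adjusted over the list alone by edgeR, and eif2ak2 was at 0.65 without passing (median 0.35, adjusted p = 0.0316). Of 40 insulin signalling genes 10 rose and 2 fell, and 11 and 2 adjusted over the list alone (foxo1a 1.14, rps6kb1a 0.98; median 0.12, adjusted p = 0.0481).

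A further 21 lists did not pass over time in PBS (adjusted p from 0.0941 to 0.904). Of their genes 4 rose and 3 fell of 37 FoxO targets (6 and 6 adjusted over the list alone; fbxo32 1.36), 5 and 0 of 27 pattern recognition genes (6 and 2; ripk2 1.11). They were 4 and 1 of 29 hypoxia genes (6 and 2), 3 and 4 of 41 heat-shock genes (3 and 6; bag3 0.75) and 1 and 2 of 18 gluconeogenesis genes (2 and 2). The counts were the same adjusted over the list alone for the inhibitors of insulin signalling (4 and 3 of 36; ptpn1 0.75), glycolysis (3 and 1 of 43), fatty acid oxidation (3 and 3 of 28; cpt1b 0.59), lens (4 and 2 of 49; opn1sw2 -0.65), erythroid (2 and 1 of 24; fech 1.54) and macrophage (1 and 2 of 25; CD68 -0.53) lists. They were also the same for the lymphoid (0 and 2 of 15), glucocorticoid (2 and 0 of 22), acute-phase (1 and 0 of 45), intestine (1 and 0 of 20), liver (0 and 0 of 37) and neuron (0 and 0 of 35) lists. They were 3 and 0 of 28 in cholesterol synthesis (2 and 0 adjusted over the list alone), 2 and 0 of 40 in growth (1 and 0), 1 and 0 of 30 in exocrine pancreas (0 and 0) and 1 and 0 of 23 in islet (0 and 0). The medians lay between -0.35 for the erythroid and 0.13 for the glucocorticoid list. The median was below 0 and the mean above it for the FoxO (-0.02 and 0.05), fatty acid (-0.06 and 0.02) and intestine (-0.02 and 0.07) lists, and above and below for gluconeogenesis (0.02 and -0.01). With library totals the medians of the glycolysis, fatty acid, FoxO, acute-phase, intestine and neuron lists were above 0, against below 0 with TMM. Among the 12 libraries that do not stand apart 4 of these 21 lists passed over time. They were growth (16 up and 0 down, adjusted p = 2.61e-06) and cholesterol synthesis (12 up and 0 down, adjusted p = 0.000211), both up, and lens (median -0.26, adjusted p = 0.00436) and heat-shock (-0.14, adjusted p = 0.0207), both down. With an estimated correlation none of the 4 passed (adjusted p = 0.469 for each). The insulin signalling list, which passed in all 16, did not (adjusted p = 0.0557).

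The genes behind counts of 5 or fewer over time in PBS were likewise chosen after their values were seen, where the fixed rule did not name them. In metabolism hk2, pfkfb3, MLXIPL, FDFT1, hmgcrb, pparda and pparab rose, and fbp2, fbp1a, acss2, acads, hadh and slc25a20 fell, with foxo1a up in gluconeogenesis and txnipb down in glycolysis. In insulin signalling and FoxO targets socs2, socs3b, ptpn11b, sqstm1, ulk1a and insrb rose, and eif4ebp1, tsc2, inpp5d, socs7, cdkn1a, klf11a, klf11b and the second ptpn6 identifier fell. In the stress, growth and clock lists dusp5, klf6a, fosl2, nop2, gnl3, nfkbiaa, hif1aa, lepb, hsf1 and hsf2 rose, and p4ha1b, serpinh1b, chac1, hspa5, hsp90aa1.2, cry2b and nr1d1 fell. In the immune and blood lists irak3, rela, tlr5a, tlr5b, C7 (2 of 2), mmp13a, mmp9, ncf1, scpp8, irf8 and tspo rose, and mpx, npsn, cxcr4a, ccr9a and aqp1a.1 fell. Of the tissue markers lct, bhlha15, pcsk1, rlbp1b, arr3a, pde6h, gngt2a, cldni, anxa2a, cldne and timp2a rose and opn1mw1 fell.

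Over time in PBS 2946 genes passed, 13.6% of those tested, 1723 higher and 1223 lower, 488 of them by over 2-fold, and DESeq2 called 3210 (2880 shared). With library totals 75.3% of the called genes were higher, against 58.5% with TMM. Among the 12 libraries that do not stand apart 4302 genes passed (2714 shared), with the library split as a term 3361 (2824 shared) and with PBS replicates 2 and 3 at 0.5 hpi summed 1926 (1916 shared). Without PBS replicate 2 or 3 at 0.5 hpi the count was 1829 or 1852, and without PBS replicate 2 at 4 hpi 1704. Without PBS replicate 1 at 0.5 hpi the muscle list (adjusted p = 0.0631) and CD68 (0.0589) did not pass, without replicate 3 the lipogenesis list (0.0597) and without replicate 4 the neutrophil list (0.0894). Without PBS replicate 1 at 4 hpi the neutrophil (0.0839) and interferon (0.0824) lists did not pass, without replicate 2 the insulin signalling list (0.0665) and without replicate 4 CD68 (0.0573). irf3 did not pass without any 1 of the 8 PBS libraries other than replicate 2 at 0.5 hpi (adjusted p from 0.0558 to 0.122).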

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

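The tests of explanations and the counts over other splits of the samples in this part were chosen only after the results were seen; the rules for values far from their group and for differences between times were fixed before. Of 342 tests of whether 1 library lay far from the other 3 of its group, 25 found one (Dixon's gap over range), and chance gives about 1 in 20. Of these 25 values 18 came from libraries that stand apart. In PBS replicate 1 at 0.5 hpi the CPM was 49.0 for gnl3 (others 31.4 to 34.3), 45.4 for igfbp1a (90.7 to 95.0), 10.0 for cry5 (6.73 to 7.22), 11.5 for g6pca.1 (16.8 to 17.9), and 386 for txnipa (769 to 815). It was 20268 for actc1b (12647 to 13765), 155 for cebpb (276 to 297), 129 for jun (216 to 221) and 7.67 for C7 (2 of 2) (17.5 to 18.2). Its mitochondrial share was 3.97% and its most abundant gene took 1.87% of reads. In insulin replicate 1 at 4 hpi the CPM was 199 for serpinh1b (others 91.4 to 103), 12.202 for lrata (4.00 to 4.79), 117 for stmn2b (136 to 138), 3.22 for trib1 (2.27 to 2.40) and 8.45 for SNORD47 (2.92 to 3.86), and the mitochondrial share was 3.56%. In insulin replicate 1 at 0.5 hpi epcam was at 198 CPM (others 217 to 221). In libraries that do not stand apart the values were 5.41 CPM for eif2ak2 (others 1.88 to 2.25) and 24.3 for a gene with the symbol fasn (14.4 to 15.5) in PBS replicate 4 and 23.8 for ercc6 (20.4 to 20.7) in PBS replicate 3 at 0.5 hpi. At 4 hpi they were 4.69 for tagapa (3.19 to 3.30) in PBS replicate 2, 41.2 for agr2 (50.9 to 51.5) in PBS replicate 3, 0.542 for guca1a (0.772 to 0.805) in insulin replicate 2 and 63.0 for ryr1b (92.7 to 95.6) in insulin replicate 4.

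Of 110 genes named for an insulin effect, 68 had an effect that differed between 4 and 0.5 hpi (edgeR interaction, adjusted p under 0.05). Of all 21650 genes tested 2076 did (9.59%). The rule took 10 of the 110 for the smallest p in this same test, and others for their change or p at a single time. The count of 68 is thus not a result about these genes as a set. The values below are log2 effects at 4 hpi minus those at 0.5 hpi. Among clock and light-linked genes they were -2.80 for cry3, -2.53 for cry1b, -1.76 for per1b, -2.71 for per1a, -2.26 for nr1d4b, -1.99 for cry5 and -2.61 for cry-dash. Among other genes that rose at 0.5 hpi they were -1.64 for ddb2, -1.49 for ercc6, -1.47 for dhrs12, -2.55 for wdr76 and -1.56 for zufsp. Among immediate-early genes they were -2.76 for fos, -3.24 for fosb, -2.47 for fosl1a, -1.18 for junbb, -1.93 for dusp5 and 1.14 for klf2a. Among inflammatory, interferon and cytokine-signalling genes they were -2.59 for il1b, -2.45 for ptgs2b, -2.41 for mmp13a, -4.35 for irg1l, -1.53 for tnfrsf9a, -1.40 for ripk2, -1.15 for irf7, -0.95 for socs3b, -1.33 for prlrb and -1.13 for tagapa. Among metabolic and insulin-linked genes they were -1.30 for pfkfb3, -2.20 for lpin1, -0.66 for pparda, -1.08 for ppargc1b, -1.74 for fbxo32, -1.001 for foxo1a, -0.93 for sgk1, -1.25 for trib1, 2.41 for gck, 2.1003 for txnipb and 3.14 for egln3. Among chaperone and stress genes they were 3.82 for serpinh1b, 1.39 for eif2ak3, 1.93 for nupr1, -1.52 for hsf2 and -0.48 for bag3. Among growth and mitotic genes they were -0.70 for gnl3, 0.59 for bop1, 1.08 for cdc20, 0.75 for plk1 and 0.90 for tpx2. Among tissue markers they were 0.94 for hnf4a, 1.04 for gc, 0.96 for anpepb, 1.06 for sox9b, 0.70 for col17a1b, 0.98 for lgals9l1, -0.49 for sptb and -2.47 for guca1a. The remaining values were 1.73 for ptpn6 (ENSDARG00000013916), 1.78 for clk4a, 1.83 for rbm4.2, 1.33 for safb, 1.996 for ugt5d1, 2.69 for lrata, 3.07 for ponzr4, 2.86 for ZMAT1, -3.56 for plek2, -2.98 for lonrf1l and -1.80 for mcoln1a. In the 12 libraries that do not stand apart all 68 kept their sign and 53 passed. Those that did not were bag3, bop1, col17a1b, fosl1a, foxo1a, gck, il1b, irf7, mmp13a, pfkfb3, ptgs2b, sgk1, socs3b, sptb and tagapa. There 16 differences moved by over 1.5-fold: those of cry5, ddb2, egln3, fos, fosl1a, mmp13a, nr1d4b, pfkfb3, plek2, ponzr4, ptgs2b, sgk1, txnipb, ugt5d1 and wdr76, and that of irg1l, to -2.81. At 0.5 hpi irg1l was at 64.7 to 108 CPM in the 3 libraries that stand apart and 7.68 to 19.4 in the others, and its effect turned from 0.48 to -0.83 without them.

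Clock genes were lower in insulin at 4 hpi (list median -0.93), and the 4 libraries that stand apart are argued against as the source, since the median in the 12 other libraries was -0.98 (-0.983), with 39 genes down and 1 up, and the list passed there (adjusted p = 0.0426 with an estimated correlation, against 0.0726 in all 16). Collection at another phase of the daily clock could shift many clock genes at once and cannot be told apart from an effect of insulin. The 6 activator genes, which run opposite to the per genes in a cycle, had a median of -0.80 (-0.796), but over time in PBS they moved up with the list (0.46 and 0.19), so the test does not decide. Different light exposure of the pools likewise stays open at both times. Of 8 light-induced genes the median was -0.71 (-0.705) at 4 hpi, above that of the list and below 0, and 0.93 at 0.5 hpi. Insulin itself, the factor of the design, may lower these genes, and this is a hypothesis that the collection times of the pools would test.

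The 4 libraries that stand apart fall in every group but PBS at 4 hpi. Sequencing lane stays open: only 1 numbered lane, lane 5, held both kinds, with a single library that stands apart beside 4 others, and 7 libraries had no lane in the header. A swap of labels at 0.5 hpi could also not be told from the given labels: on 2834 genes scaled from 0 for PBS to 1 for insulin, PBS replicate 1 scored 0.491 and insulin replicates 1 and 2 scored 0.434 and 0.406, a difference of 0.0714 that follows neither order. Of these genes 1211 ran as labelled in the 3 libraries and 1623 the other way; single genes called with the given labels, such as pck1 (450 CPM against 232 and 273), ran as labelled but were chosen by them. Other parents or a younger stage may underlie them: erythroid markers were higher by a median of 0.72 (0.722), but with an estimated correlation the erythroid and lens lists had an adjusted p of 0.103 and the exocrine list 0.701, and the parents and exact age were not tested.

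Proinflammatory genes were lower in insulin at 4 hpi (list median -1.30), and the 4 libraries that stand apart are argued against as the source, since the median in the 12 others was -1.38, with 30 genes down and 1 up (adjusted p of the list with an estimated correlation 0.243 there and 0.241 in all 16). Fewer neutrophils and macrophages are argued against as the whole cause, since 40 markers of these cells outside the list had a median of 0.17 (0.167, quartiles -0.25 and 0.47), and 0.09 (quartiles -0.28 and 0.33; 6 rose and 4 fell) in the 12 libraries that do not stand apart. The 16 neutrophil markers among them had a median of 0.05, with 0 up and 1 down, and -0.04 (quartiles -0.31 and 0.24) in those 12, so a smaller loss of neutrophils stays open. Wounding or handling that differed between the pools could lower these genes and cannot be told apart from insulin: the lowest PBS library lay 0.54 (0.535) above the highest insulin library, less than the range of 0.674 among the PBS libraries. That insulin lowers them is a hypothesis, and it was found and tested on the same libraries.

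Other splits of the same samples into groups of the same sizes were counted for each result. At 0.5 hpi 6 of 35 splits called as many as the real 84 genes, the highest other 294, so chance is not excluded. The split with 294 put PBS replicate 1 with insulin replicates 1, 2 and 4, that is, all 3 libraries that stand apart on 1 side, and a count several times the real one points to a structure of the samples. With the library split as a term it called 8, but the term leaves such a split little to test, so this decides nothing. The 4 other splits with these 3 libraries on 1 side called 3, 8, 86 and 88 without the term. The splits that exchanged PBS replicate 1 with insulin replicate 2 or 1 called 187 and 147 genes, and 628 and 295 with the term, so the library split does not account for them, and the structure behind these counts is not settled here. With the library split as a term 2 of 35 splits reached the real 493, the highest other 628, and chance is not excluded. At 4 hpi 1 of 35 splits reached the real 6193, the highest other 0 by edgeR, and over time in PBS 1 of 35 reached 2946, the highest other 2. A share of 1 in 35 is the smallest these splits allow, and all other splits mix the groups compared. The counts argue against a random grouping, but a difference in handling or collection between the groups would give them too. For the difference between times 2 of 60 splits reached 2076, the highest other 3216. All except 3 of these broke up the groups at 4 hpi, so this decides nothing. With those groups kept, 34 of 70 assignments at 0.5 hpi reached 2076, the highest other 6730. All keep the 4 hpi effect, so this decides nothing either. For the number of lists that passed, 1 of 35 splits reached the real 19 at 0.5 hpi, the highest other 18. That margin is 1 list, and the count was 15 without PBS replicate 1, PBS replicate 4 or insulin replicate 3 and 0 by camera with an estimated correlation, so chance is not taken as excluded. It is not excluded at 4 hpi, where 23 of 35 reached 12, the highest other 17, or over time, where 16 of 35 reached 12, the highest other 15.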

How the results depend on the processing

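The alternatives with a library split, without the 4 libraries that stand apart, with summed libraries or by lane, and all tests on them, were chosen only after the data were seen. The others were fixed before, and the cause was not tested for any result that changed. For genes changed, insulin against PBS at 0.5 hpi (84), the count was 483 with DESeq2, 42 with limma voom and 131 with the filter of 10 CPM in 4 libraries. By edgeR it was 0 with only the groups compared (2115 at an unadjusted p under 0.05) and 0 with only libraries with no lane in the header (654 at an unadjusted p under 0.05). It was 493 with the library split as a term, 2844 without the 4 libraries that stand apart, 11 with PBS replicates 2 and 3 summed and 2360 with the last 2 choices together. Without 1 library it ran from 10 to 987. For genes whose insulin effect differs between 4 hpi and 0.5 hpi the count was 3448 with the split term and 1455 to 2940 without 1 library. For genes changed, PBS at 4 hpi against PBS at 0.5 hpi, it was 1926 with the summed libraries and 1704 to 4226 without 1 library. For genes changed, insulin against PBS at 4 hpi, it was 2952 in lane 5, with fewer samples, and 4517 to 6015 without 1 library. The overlap of calls between 0.5 and 4 hpi (33) was 0 by edgeR with each time fitted alone. It was 185 with DESeq2, 304 at an unadjusted p under 0.01, 177 with the split term and 1263 without the 4 libraries. With an estimated correlation the lists that passed camera numbered 0 at 0.5 hpi, 0 at 4 hpi and 0 over time (5, 4 and 1 at an unadjusted p under 0.05), and fry called 3, 15 and 12. With an estimated correlation and without the 4 libraries camera passed 2 (immediate-early and FoxO), 1 (clock) and 0 lists (6, 6 and 2 at an unadjusted p under 0.05). Without 1 library the lists numbered 15 to 19, 11 to 15 and 10 to 14. The effect of insulin on ptpn6 at 0.5 hpi, near 0, changed sign. For ENSDARG00000013916 (-0.17) it was 0.32 without the 4 libraries, 0.27 with summed libraries as well, and -0.42 to 0.0813 without 1 library. For ENSDARG00000089043 (-0.00) it was 0.03996 with library totals, 0.0120 with the replicate block and -0.14 to 0.16 without 1 library. At 4 hpi they stayed at 1.48 to 1.64 and 0.96 to 1.34 without 1 library. At 0.5 hpi the liver list (-0.09) had a median of 0.00550 without the 4 libraries and -0.13 to 0.00345 (without PBS replicate 1) without 1 library. The cartilage list (-0.06) had a median of 0.0663 without the 4 libraries and 0.0179 without insulin replicate 2. The titles share only a replicate number across groups, which does not show that libraries were paired. Of 24 pairs of libraries with the same number 9 had a correlation above 0.1, and 9 of 16 libraries correlated best with their own number. With the number as a block the counts were 103, 6490, 2278 and 3214 genes, 37 overlapping genes and 18, 13 and 12 lists. The changes of ptpn6 were then -0.16 and 0.0120 at 0.5 hpi and 1.56 and 1.15 at 4 hpi. Of 3953 further values for named genes and for lists that passed, 3514 kept their direction and side of the threshold, 346 no longer passed with the sign kept, 87 passed only under the alternative and 6 changed sign, all of them liver or cartilage list medians at 0.5 hpi. List medians with library totals are not among these values. Depth was low for ptpn6.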

Other observations

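The genes in this part, and the tests on them, were chosen only after their values were seen. Of 8 genes known to respond to light in zebrafish, 6 rose with time after injection. Over time in PBS cry5 (log2 change 1.80, adjusted p = 0.000986), cry-dash (1.70, adjusted p = 8.42e-05), ddb2 (1.55, adjusted p = 0.000203), xpc (1.17, adjusted p = 0.00739) and tefa (1.13, adjusted p = 4.00e-06) rose, and tefa was also higher in insulin at 0.5 hpi (0.77, adjusted p = 0.00626), where xpc did not pass (1.07, adjusted p = 0.0841). per2 rose over time as well (1.2004, adjusted p = 0.000285), and cry1a (0.34, adjusted p = 0.0694) and neil1 (0.21, adjusted p = 0.531) did not pass. At 4 hpi per2 (-2.33, adjusted p = 1.27e-07), cry-dash (-1.46), cry1a (-1.27, adjusted p = 9.58e-07) and tefa (-0.87) were lower in insulin. The others did not pass there, with cry5 at -0.37, ddb2 at -0.54, xpc at -0.35 and neil1 at 0.49.

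No list of RNA processing genes was tested. Single genes of this kind that were higher in insulin at 4 hpi were rbm4.2 by 1.68 (adjusted p = 1.73e-08), rbm5 by 1.65 (adjusted p = 1.82e-07), safb by 1.32 (adjusted p = 7.88e-09), and clk2a, srsf3b and srsf6a by 0.61, 0.51 and 0.46, while srsf6b was at 0.00 (adjusted p = 0.995). Of all genes tested 28.6% passed at 4 hpi. Of genes for the endoplasmic reticulum and its stress response, which were not tested as a list of their own, hsp90b1 was at 1.099 (adjusted p = 0.00165), hspa5 at 0.99 (adjusted p = 0.000158) and eif2ak3 at 0.99 (adjusted p = 4.70e-07), and the cytosolic chaperone gene hsp90aa1.2 at 1.65 (adjusted p = 0.000197). Insulin replicate 1, which stands apart, was the highest of its group for hsp90b1 (458 CPM against 192 to 233), hspa5 (487 against 284 to 307) and hsp90aa1.2 (206 against 92.7 to 111), but not for eif2ak3. The 5 photoreceptor and lens markers that rose were the cone opsin genes named above. Of the hormone genes of the islets, sst1.1 rose at 4 hpi (0.51, SE 0.18, adjusted p = 0.0382) and did not pass at 0.5 hpi (0.05, adjusted p = 0.948). ins (0.33 at 4 hpi, adjusted p = 0.0982), gcga, gcgb and sst2 did not pass at either time, and of the insulin receptor genes insrb fell at 4 hpi (-0.67, adjusted p = 0.00675) and insra was at 0.16 (adjusted p = 0.275).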
